A study of Mus musculus with 8 samples.

How the data were processed

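RNA was taken from the duodenum of mice with 2 intact copies of Zeb2 (WT) and of mice heterozygous for a Zeb2 knockout (Zeb2+/-, written Zeb2_het in the plots), with 4 libraries per genotype. Per the labels' protocols, polyadenylated RNA was selected with poly-T beads, fragmented and copied with random hexamers, and dUTP in the second strand made the libraries directional. Per the submitters' processing notes, reads were handled with HISAT2 2.0.5 and featureCounts 1.5.0-p3 on GRCm38 (mm10); the strand setting of the counting, the annotation release and any filter are not given in the sources used here. The labels describe separate samples of each genotype without stating the animal behind each library, so the p-values measure the spread between these samples, which can hold a technical part.

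The deposited values are FPKM, fragments scaled by gene length and library total as the authors' file gives them, for 54532 genes with their symbol, position, length and biotype. Of these IDs, 54495 were found in a GENCODE annotation of the same build, and 98.3% of those had the same start and end. FPKM multiplied by the deposited gene length fell on whole multiples of 1 step per library for 100% of the values above 0 (tolerance 0.01 read), so the reads per gene were rebuilt and summed to 13579347 to 17137417 per library. The library total that the authors' FPKM imply was 0.733 to 1.16 times the rebuilt sum. An extra scale factor therefore stands in the deposited FPKM, and how it was set is not given in the sources used here. No column of other samples was present.

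Values were analysed as log2(FPKM + 1). The main test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust) with genotype as the only term, on the 12190 genes with a mean FPKM of at least 1 over all 8 libraries. Genes with a Benjamini-Hochberg adjusted p below 0.05, two-sided, are called changed. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0, and their SE is limma's. A count model was not the main test because the unit is FPKM; limma voom on the rebuilt reads was run as an alternative. Zeb2 lies below the FPKM minimum, so its limma values come from a fit of all 27850 genes above 0 in any library, beside an exact two-sided permutation test of its 8 values, whose smallest possible p is 0.0286.

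Before the data were examined, 48 gene lists were written from general knowledge, covering absorption and digestion, epithelial, stromal, immune and neural cell types of the gut wall, neighbouring organs, growth and SMAD signalling, and technical classes. The 42 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 42 lists. Beside it stand camera with a correlation estimated per list and fry, a rotation test of whether a list moves one way. A list's score in a library is the mean of its members' log2(FPKM + 1) minus the WT mean of each. The count of members past the threshold is given over all genes tested and adjusted over the list alone.

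The genes named were fixed by a rule written before the data were examined. It takes Zeb2, and then, among protein-coding genes with an established symbol, past the threshold and without overlap between genotypes, the 10 with the largest positive and the 10 with the largest negative log2 fold change. For each list described it takes up to 4 members of smallest unadjusted p, and up to 4 abundant members of cell type lists. Genes named outside that rule are marked as chosen after their values were seen.

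The alternatives were another pseudocount (0.1 or 5), no filter or a mean FPKM of at least 5, scaling to TPM, by median of ratios or by quantiles, eBayes without trend and robust, array weights, the replicate number as a block, removal of pancreatic, haemoglobin and immunoglobulin genes, voom, an absolute log2 fold change of at least 1, and leaving out each library. Leaving out Zeb2+/- libraries 1 and 3 together, removing a smooth trend on gene length, and voom for Zeb2 and the lists were added after the data had been seen. Sex as a covariate was planned and not run, because all 8 libraries carried Y-linked transcripts (Ddx3y 9.13 to 12.1 FPKM) and next to no Xist (at most 0.0333 FPKM).

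The fit was tested on simulated reads for this 4 against 4 comparison, drawn with the real means and library scales for 12202 genes in the test. Their spread followed the real trend of spread on the mean, with a random factor per gene, and was the same in both genotypes. The real Zeb2+/- libraries resembled one another less (correlations 0.902 to 0.971) than the WT libraries (0.972 to 0.981). The rates below therefore hold for the simulated setting only. The fit recovered 5.97% of 67 genes changed 1.5-fold, 70.3% of 64 changed 2-fold and 93.8% of 64 changed 4-fold, and 6 of its 115 calls were genes left unchanged. With no change simulated it called 0 genes. A list of genes changed 1.5-fold was called, and 0 of 41 unchanged lists were, with genes simulated as independent of one another. Trypsins, the Defa genes and immunoglobulin V genes belong to families of near-identical copies, and the counting can have split or dropped their shared reads, so single values of these genes are uncertain while the families move together.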

Results

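The series addressed growth retardation in mice that carry 1 functional copy of Zeb2, a model of Mowat-Wilson syndrome, and asked whether the gut takes part in it. Zeb2 encodes a zinc-finger repressor that binds SMAD proteins. RNA of the duodenum was sequenced from 4 WT and 4 Zeb2+/- samples. The 8 libraries held 13579347 to 17137417 reads assigned to genes. At this depth 1 read of a gene 1 kilobase long was worth 0.0538 to 0.0885 FPKM.

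The WT libraries resembled one another more than the Zeb2+/- libraries did. Pearson correlations of log2(FPKM + 1) over 12190 genes were 0.972 to 0.981 within WT, 0.902 to 0.971 within Zeb2+/-, and 0.890 to 0.956 between genotypes. The first principal component held 42.2% of the variance and separated the genotypes. The second held 30.3% and set Zeb2+/- library 1 (score 54.1) apart from Zeb2+/- library 3 (score -38.5). No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 18.6 or more, so each library was counted once.

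**Figure D1:**
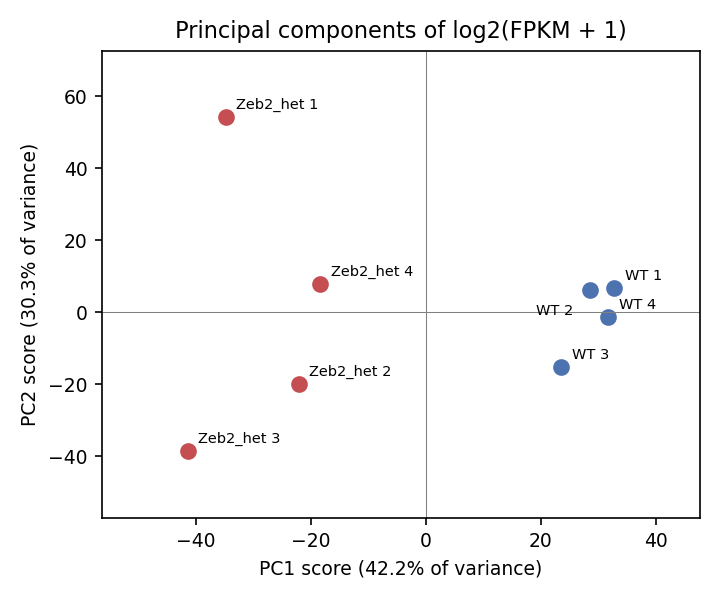
Scores of the 8 duodenum libraries on the first and second principal components of log2(FPKM + 1), with 1 point per library, WT in blue and Zeb2_het in red. The WT libraries lie together on the right, while Zeb2_het 1 and Zeb2_het 3 lie at opposite ends of the second component (54.1 and -38.5).

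Zeb2 itself (ENSMUSG00000026872, GRCm38 chromosome 2, 44983632 to 45117395, minus strand) was measured first, as a check of the genotype labels. It stood at 0.943 ± 0.192 FPKM in WT and 0.301 ± 0.146 FPKM in Zeb2+/- (SD, n = 4 each), 31.9% of the WT level. Every Zeb2+/- library (0.173 to 0.488 FPKM, 39 to 181 reads) lay below every WT library (0.760 to 1.19 FPKM, 238 to 310 reads). The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. In limma's fit of all 27850 genes the log2 fold change was -0.58 (SE 0.12), with an adjusted p of 0.0772 that did not pass the threshold. It passed in limma without trend and robust (adjusted p = 0.0417), with array weights (0.0463) and with voom on rebuilt reads (0.0110). In every other alternative fitted for Zeb2 it did not pass, with limma adjusted p from 0.0517 (without Zeb2+/- library 1) to 0.241 (replicate block).

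**Figure D2:**
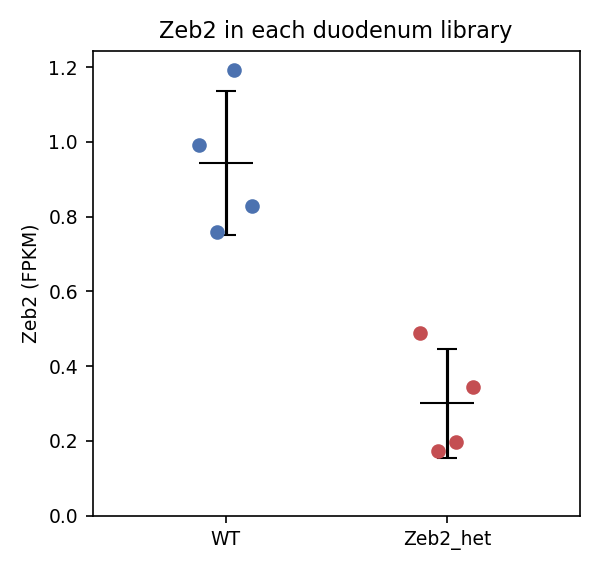
Zeb2 in FPKM for each duodenum library, with 1 point per library, the mean as a horizontal line and the SD as an error bar (n = 4 per genotype). The 4 Zeb2_het libraries (0.173 to 0.488 FPKM) lie below the 4 WT libraries (0.760 to 1.19 FPKM).

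Across the duodenum, the difference between the genotypes was mostly a loss of transcripts in Zeb2+/-. Lists of pancreatic acinar, Paneth, macrophage, fibroblast and endothelial genes were lower by camera, with 9 to 20 members of each past the threshold and adjusted p of 0.130 to 0.369 with an estimated correlation. Lists of smooth muscle, ribosomal and mitochondrial genes were shifted upward by camera, with Hspb6 their only member past the threshold and adjusted p of 0.514 to 0.572 with an estimated correlation. In the main test 0 genes and 0 of 5 lists of nutrient absorption passed. Of 12190 genes, 395 changed, 57 higher and 338 lower in Zeb2+/-. The lower genes were 258 protein-coding genes, 70 immunoglobulin V genes of 147 tested, and 10 of other classes. Their median log2 fold change was -1.52, against 0.78 for the higher genes. In 394 of the 395 the 4 libraries of one genotype lay above all 4 of the other, as did 14.5% of all tested genes, where chance gives 2.86%. The count fell to 218 without WT library 1, 253 without WT library 2 and 225 without WT library 4. All 395 kept the sign of their fold change, which leaving out a library cannot turn for the 394 without overlap. The higher genes were the less stable part, with 15 under TPM scaling, 29 under median of ratios and 94 under quantile normalization. With array weights 493 were higher and 694 lower, 58.5% lower against 85.6% in the main test.

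**Figure D3:**
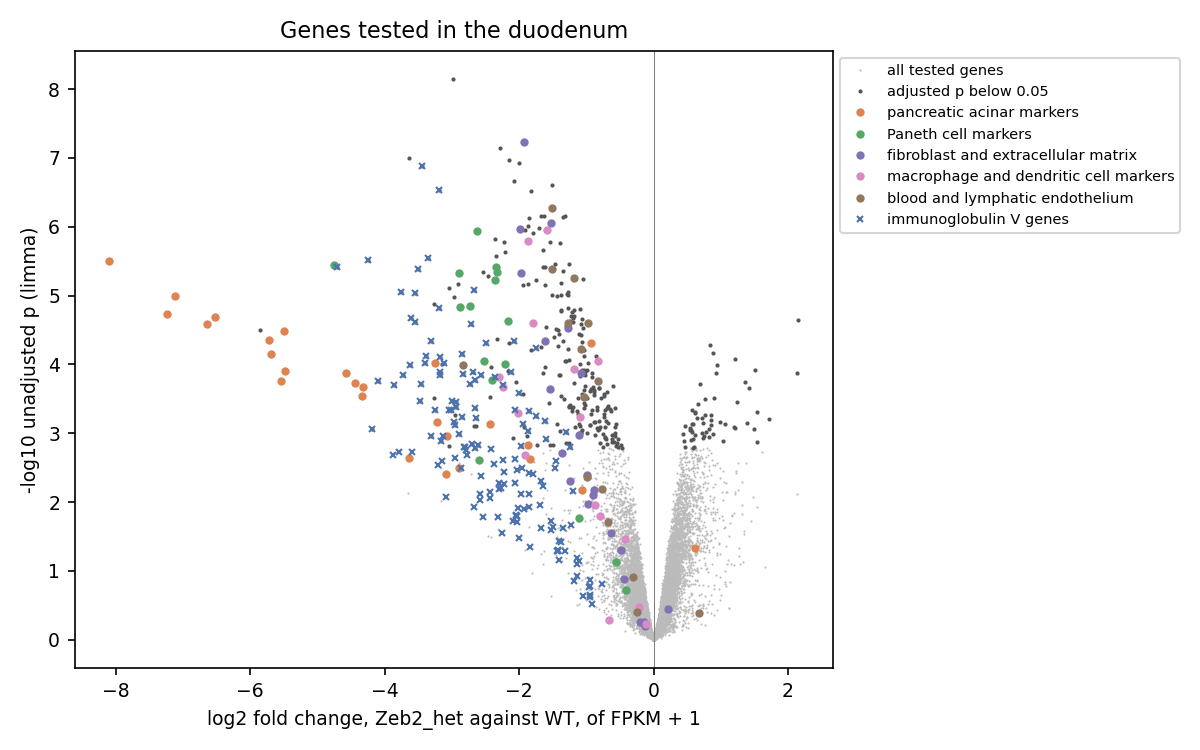
Log2 fold change (Zeb2_het against WT, of FPKM + 1) on the horizontal axis against -log10 of limma's unadjusted p, with 1 point per tested gene (12190) and marker groups in colour. Most of the 395 genes past the threshold lie to the left of 0, with the pancreatic acinar genes farthest left.

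The 10 largest rises were modest. Aqp8, a water channel, rose from 0.996 ± 0.380 to 4.50 ± 1.87 FPKM (log2 fold change 1.42, SE 0.24, adjusted p = 0.0131), and Pcp4, a calmodulin-binding peptide, from 1.01 ± 0.419 to 3.63 ± 0.718 FPKM (1.22, SE 0.18, adjusted p = 0.00727). Hspb6, a small heat shock protein of muscle, rose from 3.54 ± 0.573 to 7.35 ± 0.940 FPKM (adjusted p = 0.00632), and Smim22, a small membrane protein, from 80.3 ± 9.85 to 171.1 ± 51.7 FPKM (adjusted p = 0.0434; SD, n = 4 throughout). The other genes among the 10 were Arhgef39, Gcat, Rbpms2, Pnp2, Nrbp2 and Bloc1s4, with log2 fold changes of 0.78 to 0.95 and adjusted p of 0.00825 to 0.0388. Gcat shares its span with a second annotated gene of the same symbol. Bloc1s4, Nrbp2, Pnp2, Rbpms2 and Smim22 lost the threshold without any 1 WT library and without Zeb2+/- library 2 or 3, Rbpms2 and Smim22 also without Zeb2+/- library 1, and Aqp8 without WT library 4 (adjusted p = 0.0520). Under TPM scaling Arhgef39, Bloc1s4, Gcat, Nrbp2, Rbpms2 and Smim22 lost it. Pcp4 passed in each alternative in which it was tested. Hspb6 did so too, except that its log2 fold change of 0.88 lay below the fold minimum of 1.

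The 10 largest falls were all digestive enzymes of the exocrine pancreas. Ctrb1, a chymotrypsinogen (chromosome 8, 111686519 to 111691010), fell from 535.9 ± 361.6 to 0.430 ± 0.613 FPKM (SD, n = 4; log2 fold change -8.10, SE 0.77, adjusted p = 0.00107). The trypsins Try4, Prss2 and Try5, the lipases Pnlip and Cel, the elastases Cela2a and Cela3b, and the carboxypeptidases Cpa1 and Cpb1 fell in the same way, with log2 fold changes of -5.48 to -7.24. All of their reads in the 4 Zeb2+/- libraries together numbered 1 for Prss2 and at most 51, for Pnlip. Of 26 tested pancreatic acinar markers, 20 fell, and 25 were lower and 1 higher when adjusted over the list alone; with voom on rebuilt reads 4 passed (Bhlha15, Cela1, Clps and Pnliprp2, named after their values were seen). Of these, Pnliprp2 lost its main call without any 1 WT library (adjusted p = 0.0676 to 0.0906) or Zeb2+/- library 2 or 4, and Cela1 without Zeb2+/- library 1 (0.0513). Bhlha15, Clps and Pnliprp2, unlike Cela1, were among the 6 acinar genes that kept at least 5% of their WT level in Zeb2+/-. The median log2 fold change of the 26 markers was -4.33 (camera adjusted p = 5.73e-25, and 0.307 with an estimated correlation). All 4 Zeb2+/- scores lay below all 4 WT scores. Acinar markers took 0.273%, 0.461%, 0.0524% and 0.475% of reads in WT libraries 1 to 4, and 0.0284% to 0.0418% in Zeb2+/-, so WT library 3 stood far below the other WT libraries. For the 10 enzymes the call was lost with voom on rebuilt reads (adjusted p = 0.0629 to 0.348, log2 fold changes -9.14 to -11.20) and without Zeb2+/- libraries 1 and 3 (0.0515 to 0.150, log2 fold changes -5.39 to -7.85).

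Paneth cells, the antimicrobial secretory cells at the crypt base, showed the next largest fall. Of 16 tested markers 12 fell, and 14 when adjusted over the list alone, with a median log2 fold change of -2.38 (camera adjusted p = 4.91e-20; adjusted p = 0.164 with an estimated correlation) and no overlap of scores between genotypes. Itln1, a lectin that binds microbial sugars, fell from 371.8 ± 115.6 to 57.8 ± 8.52 FPKM (adjusted p = 0.000596). Ang4, an antimicrobial ribonuclease, fell from 122.0 ± 51.6 to 4.003 ± 2.98 FPKM (adjusted p = 0.00111), and the alpha-defensin Defa22 from 31.3 ± 9.16 to 5.34 ± 1.495 FPKM (adjusted p = 0.00111; SD, n = 4). Of the 13 tested genes of the antimicrobial and microbiota-responsive list, only Itln1 and Ang4 passed, and the list did not (median -0.07, adjusted p = 0.267), except without Zeb2+/- library 2 (-0.68, 0.0310).

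Markers of immune cells of the mucosa were lower for several lineages. Of 16 macrophage and dendritic cell markers 9 fell, and 13 adjusted over the list alone (median -1.13, camera adjusted p = 2.77e-13; adjusted p = 0.130 with an estimated correlation). Among them were Cd209a, a lectin (2.20 ± 0.278 to 0.0675 ± 0.0711 FPKM), Adgre1, which encodes F4/80 (3.93 ± 0.606 to 0.363 ± 0.257 FPKM), and the adaptor Tyrobp (19.4 ± 1.73 to 5.17 ± 2.13 FPKM), with adjusted p of 0.000587 to 0.00315. Of 11 plasma cell markers 2 fell, and 7 when adjusted over the list alone (median -1.18, camera adjusted p = 1.11e-05; adjusted p = 0.514 with an estimated correlation). These 2 were Igha, the constant region of IgA (1316 ± 281.1 to 173.6 ± 126.8 FPKM, adjusted p = 0.0164), and Jchain (289.0 ± 58.2 to 54.9 ± 32.1 FPKM, adjusted p = 0.0308). Immunoglobulin genes took 0.584 ± 0.139% of reads in WT and 0.104 ± 0.0654% in Zeb2+/- (exact permutation p = 0.0286). Of 21 T cell and intraepithelial lymphocyte markers 3 fell, also when adjusted over the list alone. They were Itgae, the integrin that holds lymphocytes in the epithelium (8.41 ± 0.590 to 2.62 ± 0.996 FPKM), Cd160 and Cd3e (list median -0.46, camera adjusted p = 5.37e-05; adjusted p = 0.130 with an estimated correlation). The scores of these lists did not overlap between genotypes. The Igha call was lost without WT library 1, without WT library 4 and without Zeb2+/- library 1, at adjusted p of 0.0587 to 0.0614. Cd160 was lost without any 1 WT library, Cd3e also without Zeb2+/- library 3 or 4, and Jchain without any 1 WT library or Zeb2+/- library 1 or 4 (0.0592 to 0.0983) and with voom on rebuilt reads (0.0801).

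B cell markers and MHC class II genes did not pass in the main test (medians 0.68 and 0.18, adjusted p = 0.158 and 0.970) and differed between libraries within a genotype. The B cell list was higher and past the threshold in 6 of 24 alternatives, among them without WT library 2 (0.97, adjusted p = 0.0306), without Zeb2+/- library 2 (1.13, 0.00833) or 3 (1.19, 0.00492), and under TPM scaling (0.74, 0.0270). MHC class II passed without Zeb2+/- library 3 (0.49, 0.0399). B cell scores were 2.57 and 1.99 in Zeb2+/- libraries 1 and 4, against -0.94 and -1.07 in Zeb2+/- libraries 2 and 3. Both mast cell proteases measured above the minimum, Mcpt1 and Mcpt2, fell (log2 fold changes -1.42 and -1.09, adjusted p = 0.00539 and 0.0354); their list was too short to be tested, and both were chosen after their values were seen. Mcpt2 lost its call in 13 of 21 alternatives, among them without WT library 1 (adjusted p = 0.127), 2 (0.0999) or 4 (0.104), without Zeb2+/- library 1 (0.0506), 2 (0.0687) or 3 (0.0738), and with voom (0.0882).

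Stromal and vascular transcripts fell as well. Of 22 fibroblast and extracellular matrix genes 9 fell, and 16 adjusted over the list alone (median -1.04, camera adjusted p = 2.14e-14; adjusted p = 0.369 with an estimated correlation). Col14a1, a fibril-associated collagen, fell from 5.41 ± 0.809 to 0.670 ± 0.0837 FPKM (adjusted p = 0.000226). Pdgfrb, the receptor of platelet-derived growth factor on mesenchymal cells, fell from 4.12 ± 0.388 to 0.784 ± 0.234 FPKM, and the type VI collagen genes Col6a2 and Col6a1 from 11.3 ± 1.82 to 2.11 ± 0.667 FPKM and from 23.9 ± 3.90 to 5.47 ± 1.90 FPKM (adjusted p = 0.000587 to 0.00115; SD, n = 4). Of 15 markers of blood and lymphatic endothelium 9 fell, and 12 adjusted over the list alone (median -0.99, camera adjusted p = 8.36e-14; adjusted p = 0.173 with an estimated correlation). Kdr, the main VEGF receptor of vessels, fell from 3.43 ± 0.318 to 0.554 ± 0.133 FPKM, Mmrn1 from 3.43 ± 0.694 to 0.540 ± 0.151 FPKM, Tie1 from 2.84 ± 0.340 to 0.691 ± 0.144 FPKM and Eng from 6.26 ± 0.533 to 2.06 ± 0.716 FPKM (adjusted p = 0.000533 to 0.00315). Scores of both lists lay lower in all 4 Zeb2+/- libraries than in any WT library. Of the 5 tested mesenchymal transition regulators only Mmp2, a gelatinase, fell (9.83 ± 1.19 to 1.37 ± 0.689 FPKM, adjusted p = 0.000704), and the list did not pass camera (median -0.40, adjusted p = 0.0722; fry adjusted p = 0.0316; without Zeb2+/- library 1 -0.75, 0.00617).

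**Figure D4:**
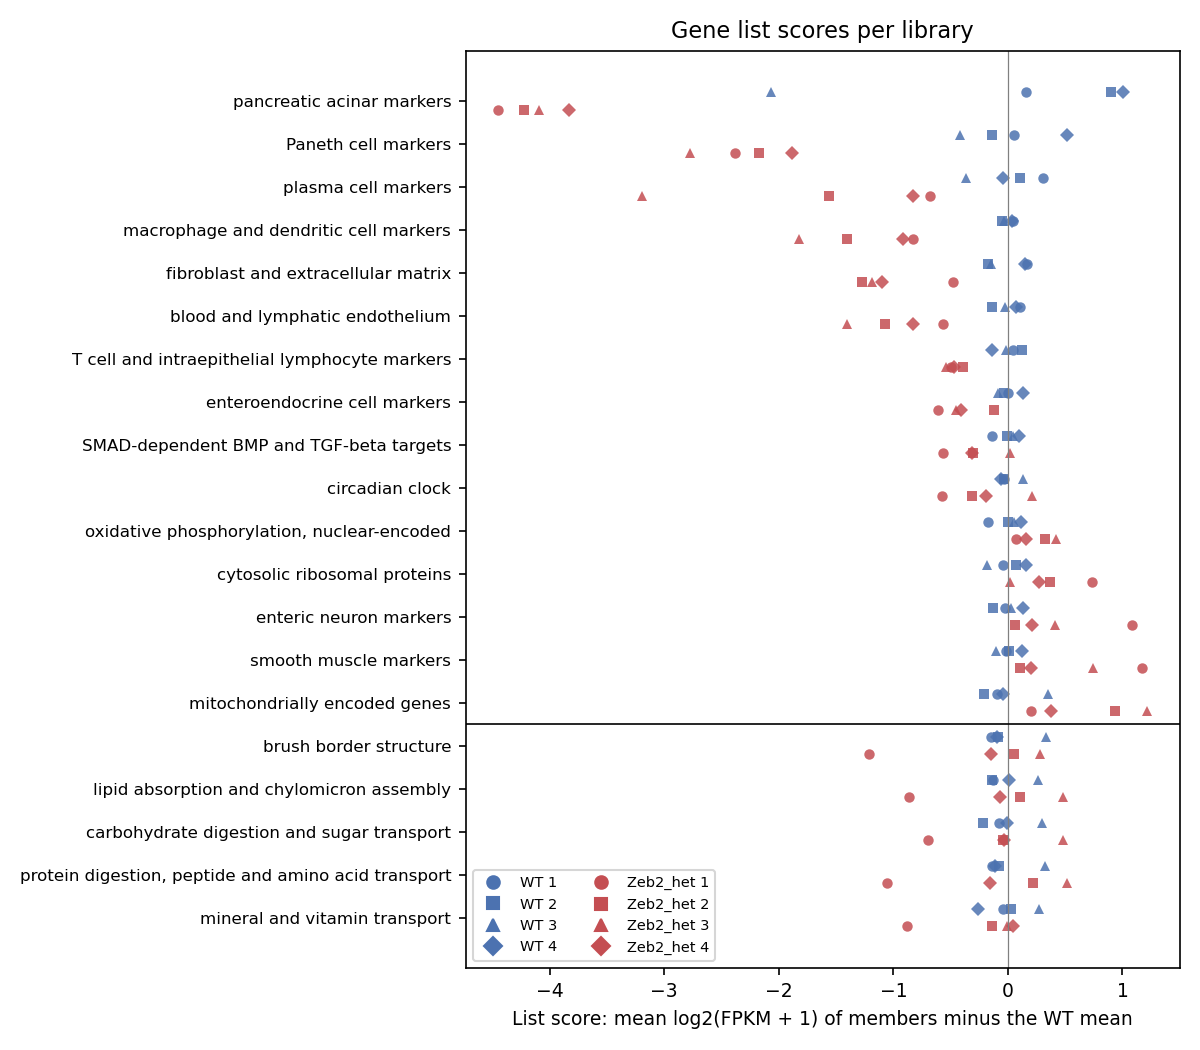
Score of each gene list in each library, as the mean log2(FPKM + 1) of its members minus the WT mean, with 1 marker per library, WT in blue and Zeb2_het in red; lists above the line passed camera's threshold at its preset correlation, 0 of them with an estimated one, and the 5 below it are absorption lists that did not pass. Acinar, Paneth, plasma cell, macrophage, fibroblast, endothelial, T cell and enteroendocrine scores lie lower in every Zeb2_het library than in any WT library, while Zeb2_het 1 alone lies far to the left for the absorption lists.

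Muscle and nerve did not follow the stroma. Smooth muscle markers shifted upward as a list (18 tested, median 0.60, camera adjusted p = 1.06e-05; adjusted p = 0.554 with an estimated correlation), with Hspb6 alone past the threshold and 4 higher and 1 lower when adjusted over the list alone. Cnn1, a calponin, stood at 16.3 ± 2.63 and 32.6 ± 14.1 FPKM and Mylk, myosin light chain kinase, at 30.7 ± 1.30 and 44.3 ± 9.09 FPKM in WT and Zeb2+/- (adjusted p = 0.131 and 0.139). Enteric neuron markers shifted upward too (13 tested, median 0.54, camera adjusted p = 0.00886; adjusted p = 0.645 with an estimated correlation). By limma and by voom 0 of them passed, also when adjusted over the list alone, and 7 were higher at an unadjusted p below 0.05, with Tubb3 at 2.30 ± 0.365 and 5.21 ± 2.17 FPKM and Gal at 1.71 ± 0.311 and 5.08 ± 3.04 FPKM (adjusted p = 0.0833 and 0.126). Tubb3 passed with array weights (0.00618) and without Zeb2+/- library 2 (0.0458). Scores were highest in Zeb2+/- library 1 (1.17 for muscle, 1.08 for neurons). Without that library the neuron list no longer passed (median 0.32, adjusted p = 0.108), and without Zeb2+/- libraries 1 and 3 neither did (smooth muscle 0.21, adjusted p = 0.0673; neurons 0.24, adjusted p = 0.257).

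Ribosomal, oxidative phosphorylation and mitochondrially encoded lists were shifted upward by camera at its preset correlation. The ribosomal and mitochondrially encoded lists had been written as technical classes. The medians were 0.34 for 76 cytosolic ribosomal proteins (camera adjusted p = 3.58e-11; adjusted p = 0.572 with an estimated correlation), 0.28 for 76 nuclear-encoded genes of oxidative phosphorylation (4.12e-10; adjusted p = 0.554 with an estimated correlation) and 0.67 for 13 mitochondrially encoded genes (1.11e-05; adjusted p = 0.514 with an estimated correlation). By limma 0 members of these 3 lists passed on their own, with 25, 27 and 6 higher at an unadjusted p below 0.05, and by voom 0, 1 (Ndufa5) and 0 passed. Adjusted over the list alone 0, 5 and 3 were higher. Ndufa5, a subunit of complex I, stood at 58.8 ± 5.38 and 92.0 ± 13.4 FPKM (adjusted p = 0.0572), Rpl41 at 293.2 ± 28.4 and 497.7 ± 117.3 FPKM (adjusted p = 0.0804) and mt-Nd1 at 6495 ± 441.2 and 11062 ± 2624 FPKM (adjusted p = 0.131). The ribosomal median dropped to 0.22 without Zeb2+/- library 1 and to 0.21 with pancreatic, haemoglobin and immunoglobulin genes removed, the oxidative phosphorylation median to 0.14 under that removal, and the mitochondrial median to 0.45 under quantile normalization; all 3 lists stayed past camera's threshold there. With array weights Ndufa5 (0.0160), Rpl41 (0.0337) and mt-Nd1 (0.0243) passed. Mitochondrially encoded genes took 5.08 ± 0.235% of reads in WT and 7.75 ± 0.605% in Zeb2+/- (exact permutation p = 0.0286).

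Nutrient absorption was the question behind the tissue, and none of its lists passed in the main test. These were lipid absorption and chylomicron assembly (29 genes, median -0.10, camera adjusted p = 0.703), carbohydrate digestion and sugar transport (16, -0.07, 0.827), protein digestion with peptide and amino acid transport (21, -0.07, 0.721), mineral and vitamin transport (19, -0.17, 0.266) and brush border structure (16, -0.23, 0.139). The brush border list was lower and past the threshold in 4 of 24 alternatives: TPM scaling (0.0381), quantile normalization (0.00458), removal of pancreatic, haemoglobin and immunoglobulin genes (0.0233), and without Zeb2+/- library 3 (0.00911). By limma 0 of their 101 members passed, also when adjusted over each list alone, and by voom 0 did. At an unadjusted p below 0.05 limma had 3 lower and 1 higher. Without Zeb2+/- library 4, Scarb1 (adjusted p = 0.0288) and Cybrd1 (0.0424) were lower and past the threshold. In the lipid list the members of smallest unadjusted p were Scarb1, a lipoprotein receptor (4.89 ± 1.03 in WT and 2.60 ± 1.57 FPKM in Zeb2+/-, adjusted p = 0.169), and Dgat2, an enzyme of triglyceride synthesis (400.0 ± 74.8 and 245.3 ± 122.9 FPKM, 0.273). In the other 4 lists, in the order above, it was Tkfc, a kinase of fructose metabolism (224.2 ± 30.8 and 174.0 ± 43.7 FPKM, 0.378), Tmprss15, enteropeptidase (80.9 ± 24.9 and 48.7 ± 29.0 FPKM, 0.419), Cybrd1, a duodenal iron reductase (1.54 ± 0.363 and 0.521 ± 0.353 FPKM, 0.0803), and Myo7b, a myosin of microvilli (146.2 ± 34.0 and 105.7 ± 45.7 FPKM, 0.447). Zeb2+/- library 1 had the lowest score for each of the 5 lists, from -1.21 for the brush border to -0.70 for carbohydrates, while the other 3 Zeb2+/- libraries scored between -0.16 and 0.51.

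Other epithelial lists gave few single genes. Of 16 enteroendocrine markers 2 fell, and 4 adjusted over the list alone (median -0.32, camera adjusted p = 0.000409; adjusted p = 0.514 with an estimated correlation), with no overlap of scores. These 2 were Gcg, which encodes proglucagon (7.03 ± 1.37 to 2.13 ± 0.922 FPKM, adjusted p = 0.00967), and the granin Chgb (36.4 ± 3.05 to 17.3 ± 4.96 FPKM, adjusted p = 0.0151), the latter lost without WT library 1 (0.0507), 3 (0.0501) or 4 (0.0596). Goblet cell markers (median -0.24), intestinal stem cell markers (-0.17), epithelial junctions (-0.08), bile acid handling (-0.10), xenobiotic metabolism (-0.23) and duodenal identity (-0.23) did not pass, at adjusted p of 0.0513 for xenobiotic metabolism and 0.110 to 0.937 for the rest. The xenobiotic list was lower and past the threshold in 13 of 24 alternatives (adjusted p down to 0.00119, under quantile normalization). So were goblet cells without Zeb2+/- library 2 (0.0242) and with the gene length trend removed (0.0237), stem cells without Zeb2+/- library 1 (0.0461) and with no filter (0.00851), and duodenal identity without Zeb2+/- library 4 (0.0306). By limma and by voom 0 of their members passed; at an unadjusted p below 0.05 limma had 1, 3, 1, 0, 3 and 1. The lists of tuft cells (median -0.01, adjusted p = 0.937), ileal identity (-0.29, 0.107), interferon response (-0.13, 0.214) and proliferation (0.04, 0.468) did not pass in the main test either, but single members did. Interferon response was lower and past the threshold without WT library 1 (-0.42, adjusted p = 3.67e-05), proliferation was higher without Zeb2+/- library 3 (0.29, 1.15e-06), and ileal identity was lower without WT library 2 (-0.39, 0.0401) or Zeb2+/- library 3 (-0.47, 0.0399). Ptgs1, cyclooxygenase 1 of tuft cells, fell from 6.60 ± 0.531 to 4.02 ± 0.342 FPKM (adjusted p = 0.0125), and the ileal gene Mptx1 fell from 1.75 ± 0.452 to 0.279 ± 0.143 FPKM (adjusted p = 0.00976). The interferon-induced GTPases Gbp2 and Iigp1 fell (adjusted p = 0.00811 and 0.00865), and Birc5, survivin of dividing cells, rose from 4.60 ± 0.750 to 8.44 ± 1.86 FPKM (adjusted p = 0.0385). The Birc5 call was lost under TPM scaling (0.189), median of ratios (0.150) and without any 1 WT library, and Ptgs1 and Mptx1 lost theirs without WT library 4 (0.0551) and WT library 1 (0.0519).

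For growth and for SMAD signalling, which Zeb2 restrains, 1 gene of each list passed. Both genes fell. The fibroblast (median -1.04) and endothelial (-0.99) lists were lower in the same libraries, and whether the genes fell along with those cell types was not tested. Igfbp3, a carrier protein of insulin-like growth factors (chromosome 11, 7206086 to 7213923), fell from 25.5 ± 2.96 to 2.35 ± 0.532 FPKM (SD, n = 4; log2 fold change -2.99, SE 0.14, adjusted p = 8.65e-05). It was the only one of 12 genes of the growth hormone, IGF and insulin axis to pass, also when adjusted over the list alone (list median -0.02, camera adjusted p = 0.206, fry adjusted p = 0.0316). Igfbp7 stood at 65.8 ± 9.68 and 34.6 ± 23.1 FPKM (adjusted p = 0.173). Without Zeb2+/- library 1 the list (-0.16, adjusted p = 0.0387) and Igfbp7 (-1.49, 0.0173) passed as lower. Bmp4, a bone morphogenetic protein, fell from 5.18 ± 0.520 to 1.55 ± 0.475 FPKM (adjusted p = 0.00174). It was the only one of 12 SMAD-dependent BMP and TGF-beta targets to pass, 2 being lower when adjusted over the list alone (median -0.23, camera adjusted p = 0.0342; adjusted p = 0.554 with an estimated correlation). Of the 12, 10 had a negative fold change, and the list lost its call without WT library 4 (adjusted p = 0.0828) and without Zeb2+/- library 1 (0.109), 2 (0.0626) or 4 (0.0660), and at a mean FPKM of at least 5 (0.223).

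The circadian clock list, a sign of sampling time, passed narrowly (18 genes, median -0.18, camera adjusted p = 0.0342; adjusted p = 0.691 with an estimated correlation). By limma and by voom 0 of its genes passed, also when adjusted over the list alone, and 4 were lower at an unadjusted p below 0.05, with Per1 at 11.1 ± 3.07 and 6.84 ± 1.65 FPKM (adjusted p = 0.168; 0.0481 under TPM scaling). The list lost its call without WT library 3 (adjusted p = 0.0731), Zeb2+/- library 1 (0.222) or Zeb2+/- library 2 (0.0703). Over all 24 alternatives, camera with an estimated correlation and fry included, its median ran from -0.35 to -0.06 and its adjusted p from 0.000185 to 0.691. The remaining lists did not pass in the main test: cholesterol synthesis (median 0.05), fatty acid synthesis (-0.02), fatty acid oxidation and PPAR targets (-0.04), the unfolded protein and amino acid stress response (-0.06, with a mean of 0.01 and 3 genes higher and 1 lower when adjusted over the list alone), immediate early genes (-0.44), histone genes (0.31) and adipocyte markers (0.43), at adjusted p of 0.110 to 0.951. Immediate early genes were lower and past the threshold in 6 of 24 alternatives, among them without WT library 1 (-0.46, adjusted p = 0.0265) or 2 (-0.51, 0.0313) and without Zeb2+/- library 3 (-0.46, 0.0452). Over all 42 lists, 15 passed camera at its preset correlation, 10 lower and 5 higher, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.130 and 5 lists had an unadjusted p below 0.05. Fry passed 8, of which 6 were among the 15: acinar, Paneth, fibroblast, endothelial, macrophage and T cell (adjusted p = 0.00163 to 0.00816). The other 9 of the 15 did not pass fry: enteroendocrine (0.0614), plasma cell (0.0686), mitochondrially encoded (0.0959), oxidative phosphorylation (0.122), SMAD targets (0.136), smooth muscle (0.168), ribosomal (0.206), enteric neuron (0.2998) and clock (0.412). Brunner gland (3 genes above the minimum), enteric glia (4), interstitial cells of Cajal (4), haemoglobin (2), mast cells (2) and gastric markers (0) were too few to test.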

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

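The tests of the acinar members near 0 in Zeb2+/-, of scaling, of allele loss and cell share for Zeb2, and of gene length, tissue share and 2 left-out libraries for the cell type lists were chosen after the result was seen.

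The pancreatic acinar genes were the strongest pattern. Against pancreatic tissue carried along with the WT samples, the first test gave an SD of 1.40 for the log2 ratio of WT library 3 to the other WT libraries over 24 acinar genes, above the bound of 1; that bound was wrong, because 6 of the genes, Spink1 first, are carried by the Zeb2+/- libraries themselves and 79.4% of the acinar reads left there are Spink1. Over the 18 genes below 5% of the WT level in Zeb2+/- the SD was 0.43, against ratios of -2.60 to 0.28 for the other 6. The 18 were picked by the fall itself, so this SD does not settle the source. Over all 24 genes, a set not picked by the fall, the median ratio was -3.54, or 11.6-fold lower in WT library 3. Genotype cannot account for that difference, which lies within WT, and its cause was not tested. Scaling is argued against, since the median stayed at -4.33 or lower under 3 other scalings. Pancreas taken with the WT duodenum remains open, and genotype does as untested biology; insulin reads (8, 22, 0 and 0 in WT, 0, 0, 0 and 3 in Zeb2+/-, exact p = 0.429) were too few to decide.

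Zeb2 stood at 31.9% of WT. Loss of 1 allele as the whole cause cannot be told apart from a larger loss: doubled Zeb2+/- values were 0.601 ± 0.292 against 0.943 ± 0.192 FPKM (SD, n = 4; exact p = 0.114), and 4 against 4 is too few to settle it. Fewer stromal, endothelial and myeloid cells, which carry Zeb2, could also account for the fall: Zeb2 minus the score of those lists differed by 0.05 (exact p = 0.771), which does not show that the difference is 0. Both stay open, genotype included.

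The fibroblast, endothelial, macrophage and Paneth lists were lower by camera at its preset correlation, and not past the threshold with an estimated one (adjusted p = 0.130 to 0.369). Gene length as the whole cause is argued against by the list medians. Under every alternative tested, a length correction included, they stayed at or below -0.61 (fibroblast), -0.46 (endothelial), -0.51 (macrophage) and -1.82 (Paneth). After that correction, under which 323 of the 395 genes were called again, 4 of the 4 lists also stayed past camera's threshold. Passing it decides little alone, because the lists do not pass with an estimated correlation. A lower share of all tissue outside the epithelium is argued against, since smooth muscle minus fibroblast scores were 1.30 to 1.93 in Zeb2+/- and -0.19 to 0.18 in WT (exact p = 0.0286). Zeb2+/- libraries 1 and 3 alone are argued against too, since the scores of Zeb2+/- libraries 2 and 4 lay below all WT scores in each list. Without libraries 1 and 3, 4 of the 4 lists stayed past camera's threshold at its preset correlation. Which layer or stretch of the duodenum was sampled was not tested and stays open, as does genotype.

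A further 21 of 272 groups of 4 libraries, where chance gives about 13.6, held 1 library far from the other 3, by a gap to the nearest above the 95% limit of Dixon's test; the values in parentheses are that gap over the range. WT library 3 was high for the scores of protein digestion (0.871), brush border (0.879), bile acid handling (0.950) and circadian clock (0.835) and for Cdh1 (0.844). Zeb2+/- library 1 was low for goblet cells (0.866), and Zeb2+/- library 3 was low for stem cells (0.849), Tie1 (0.842) and Iigp1 (0.874) and the only one with Prss2 (1). Zeb2+/- library 4 was high for Pnlip (0.933), Cela2a (0.866) and Wnt4 (0.874) and the only Zeb2+/- library with Cpa1, Try5, Cela3b and Tff2 (1 for each). In WT, library 1 was high for Col14a1 (0.912), library 2 low for Mmrn1 (0.955) and Aldh1a3 (0.882), and library 4 low for Aldh1a2 (0.880).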

How the results depend on the processing

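The values without Zeb2+/- libraries 1 and 3, with the gene length trend removed, and with voom for Zeb2 and the lists were chosen after the result was seen. The 395 genes kept the sign of their fold change under every alternative in which they were tested, but the count past the threshold moved. For the 394 without overlap between genotypes, left-out libraries and another pseudocount, filter, block, weighting or eBayes setting cannot turn the sign. Only alternatives that rescale or rebuild the values could have turned it, so the kept sign says little elsewhere. Against 395 changed, 57 higher and 338 lower, a mean FPKM of at least 5 gave 157, 29 and 128, with fewer genes tested, and array weights gave 1187, 493 and 694, where 58.5% were lower against 85.6%; the cause was not tested. The higher genes numbered 20 with no filter, 15 under TPM scaling, 29 under median of ratios, 94 under quantile normalization, 15 with pancreatic, haemoglobin and immunoglobulin genes removed, and 16 with an absolute log2 fold change of at least 1. Leaving out 1 library gave 218 to 487 genes, 13 to 99 higher and 205 to 388 lower, 14 to 22 lists, and Zeb2 at -0.65 to -0.52; the fewest genes came without WT library 1 (218), 4 (225) and 2 (253). Without Zeb2+/- libraries 1 and 3 there were 313 genes, 241 of them among the 395. The immediate early list (0.0309) and the interferon list (0.0498) passed with the replicate block, and proliferation with array weights (0.00245), with which the neuron list was lost (0.0561). List medians that moved by over 1.5 times, with the call kept, included T cells under TPM scaling (-0.70) and with voom (-0.76), enteroendocrine cells under TPM scaling (-0.50), with voom (-0.52) and without Zeb2+/- libraries 1 and 3 (-0.20), and smooth muscle with array weights (0.27). The pseudocount moved others by its construction. Over all alternatives the medians ran from -7.26 to -2.99 for acinar, -2.29 to -0.51 for plasma cell, -1.85 to -0.51 for macrophage and 0.23 to 0.89 for neuron markers. Of the 42 lists, 0 passed with an estimated correlation and 8 passed fry, among them the mesenchymal transition and growth axis lists, which are not among the 15. With the replicate number as a replicate block 299 genes changed, 23 higher and 276 lower, and 18 lists. Residual correlations between libraries of the same number were 0.24 for number 1 and 0.33 for number 3. Those were above every pair of unlike numbers (at most 0.20). For numbers 2 and 4 they were -0.16 and -0.19, so not every library correlated best with its own number. The lowest correlation between libraries was 0.890, and 0.847 with a pseudocount of 0.1. Over all alternatives but the fold minimum, values of named genes were on the same side of the threshold 1665 times, lost it 202 times and gained it 18 times. For lists the counts were 911, 36 and 52. Among named genes, and lists past the threshold in the main test or the alternative, 0 were reversed. A list past it in neither counted as the same whatever its direction. Medians of such lists could cross 0, as for protein digestion (-0.27 to 0.22). Zeb2, below the FPKM minimums, was fitted among all genes and has no value under the filter alternatives. Sex as a covariate was not run, since all libraries were of 1 sex. At this depth Zeb2 rested on 39 to 310 reads per library, and the simulation found 5.97% of 1.5-fold changes.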

Other observations

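The splits of the libraries were planned, and the gene families below were chosen after the result was seen, with no test of their own beyond limma's for each gene.

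Further signalling and matrix genes were lower in Zeb2+/-, all but Mmp2, Mmp7 and Bmp4 outside the tested lists. They were not tested as a group. The fibroblast (median -1.04) and endothelial (-0.99) lists were lower in the same 4 libraries, at adjusted p of 0.369 and 0.173 by camera with an estimated correlation. Of 9 matrix metalloproteinase genes tested 5 fell, Mmp10 from 18.2 ± 1.34 to 0.623 ± 0.612 FPKM (SD, n = 4; adjusted p = 0.000226) beside Mmp2, Mmp7, Mmp9 and Mmp13. Of 3 retinaldehyde dehydrogenases, the enzymes that make retinoic acid, Aldh1a2 (5.32 ± 0.274 to 1.54 ± 0.257 FPKM, adjusted p = 0.000533) and Aldh1a3 (15.1 ± 1.40 to 2.25 ± 0.906 FPKM, adjusted p = 0.000703) fell. Of 8 tested genes with a Bmp symbol, counted by name alone, Bmp4, Bmp5 and Bmp7 fell, and of 4 Wnt ligands Wnt2b and Wnt4. Hhip, an inhibitor of hedgehog ligands, fell from 2.95 ± 0.530 to 0.205 ± 0.115 FPKM (adjusted p = 0.000587), and Ptch1, the hedgehog receptor, from 3.03 ± 0.727 to 1.29 ± 0.310 FPKM (adjusted p = 0.0284). Glp2r, the receptor of the intestinal growth peptide GLP-2, fell from 1.92 ± 0.222 to 0.273 ± 0.179 FPKM (adjusted p = 0.00310). Bmp7 and Ptch1 lost the threshold without any 1 WT library (adjusted p of 0.103 to 0.175 and 0.0520 to 0.0902), and Wnt4 without WT library 1 (0.0613), 3 (0.0565) or 4 (0.0510).

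Tff2, a peptide of Brunner glands, fell from 10.7 ± 6.69 to 0.134 ± 0.267 FPKM (adjusted p = 0.00811, 0.0635 with voom on rebuilt reads and 0.134 without Zeb2+/- libraries 1 and 3). The Brunner gland markers Muc6, Aqp5, Muc5b and Bpifb1 were next to absent in both genotypes, with means of at most 0.0335 FPKM. Tff2 alone therefore does not show a fall of the gland. Of 18 mitochondrial tRNA genes 3 rose, and 0 fell.

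Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the genotypes, the real one (395, against 2 at most in any other). As 1 of 35 is the smallest share possible here, chance is unlikely for the gene count but not excluded. Every other split mixes the genotypes, so a difference between them widens its spread and lowers its count. The splits also cannot tell genotype from anything else that differed between the WT and Zeb2+/- samples. For the lists, 31 of the 35 splits gave as many (15 in the real split, 27 at most in another), so chance is not excluded for the number of lists, and libraries differ as lists along lines other than genotype.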
